A study of Homo sapiens with 6 samples.

How the data were processed

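Paired-end RNA-seq libraries were made from total RNA of H929 cells extracted with TRIzol, and sequenced on an Illumina NovaSeq, per the labels' protocols. How RNA was selected for the libraries (by poly(A) tail or by removal of ribosomal RNA) and whether the libraries kept strand are not given in the sources used here. The submitters' processing notes list fastp 0.19.5, HISAT2 2.1.0, StringTie 2.1.0 and RSEM 1.3.3, and the genome build GRCh38.p13, without roles or order. A table of estimated counts per gene was deposited, whose values are partly fractional, differ in total between libraries and were not scaled between libraries, as estimated counts from RSEM are. A second table of TPM values, which are corrected for gene length, was deposited, in which each library sums to the same total to within rounding. Both tables hold 62703 Ensembl gene IDs for 6 libraries, and every column matched a single sample by its name. Reads that fit several near-identical genes are divided among them by estimated counts, so values of such genes are uncertain.

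Groups were taken from the treatment in the labels, with 3 libraries given 1 µM Mi-2 and 3 given DMSO, all collected at 24 h. The number after the treatment in each title was used as the library's number. Pairs of libraries within a group were compared by a chi-square test of their counts, which gave 16.6 to 23.4 per degree of freedom, so all were kept as separate samples. Gene names came from a table of Ensembl IDs and symbols for 62625 of the IDs and from GENCODE release 29 for a further 72, and 6 had no name. Coordinates, gene types, lengths and GC content are those of GENCODE release 29 on GRCh38, which holds 58279 of the IDs, and may differ from the annotation release used for counting.

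Estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 16082, and libraries were scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) compared Mi-2 with DMSO in all 6 libraries, with no other term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were computed from the fold change and its F statistic. CPM values are normalised by TMM. The biological coefficient of variation was 14.2% and total counts ran from 19980700 to 23756700, so small changes of genes with few counts could not be detected.

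Before the data were examined, 25 gene lists, the named-gene rule, the tests of genes and lists and the alternatives were fixed, except where another choice is stated to have been made later. The lists were NF-κB targets, components of the BCMA, BCL10 and MALT1 pathway, immunogenic cell death and danger signals, the unfolded protein response, the integrated stress response, NRF2 targets, heat shock, metallothioneins and zinc, plasma cell and myeloma identity, G2 and mitosis, DNA replication, MYC and ribosome biogenesis, p53 targets, the BCL2 family with caspases and death receptors, cholesterol synthesis, interferon-stimulated genes, antigen presentation, proteasome subunits, glycolysis and hypoxia, autophagy and lysosome, mitochondrially encoded mRNAs, and markers of T and NK cells, of myeloid cells, of fibroblasts, endothelium and epithelium, and of erythroid cells and platelets. Some genes stand in several lists, such as 9 of the 33 measured danger signal genes, and the 4 lists of other cell types share no measured gene with another list. Each was tested with camera on the edgeR fit (preset correlation 0.01), adjusted over the 25 lists, and again with an estimated correlation and with fry (limma 3.58.1). Named genes were the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05, an average log2 CPM of at least 2 and separate CPM ranges. To these were added genes fixed in advance, among them TNFRSF17, MALT1, BCL10, NFKBIA, TNFAIP3, CALR, HMGB1, MYC and IRF4, up to 4 called members per list and direction with an average log2 CPM of at least 1, and markers of other cell types with an average log2 CPM of at least 2, which gave 96 genes.

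The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, removal of immunoglobulin genes and the 20 genes with the highest counts, limma with a trend on log2 of the deposited TPM values plus 1 or plus 0.1 (mean TPM of at least 1) or plus 1 with no TPM filter, the library number as a block, and each library left out in turn. Fold changes of the TPM fits are on the log2(TPM + pseudocount) scale, which understates changes of low genes.

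The tests were checked on simulated counts with the means, library sizes and spread of the real libraries and 200 genes changed. With 1777 genes called in the real data, the share of changes recovered there may differ, since it depends on how many genes change. Of the genes changed 1.5-fold edgeR recovered 36% and of those changed 2-fold 76%, with 9 false calls (7.26% of its calls) among 15783 simulated genes, and DESeq2 recovered 52% and 81% with 31 false calls (18.2%). Limma-voom recovered 36% and 74% with 6 false calls, and limma on log2(TPM + 1) 13% and 60% with 3. Both camera settings and fry called the single list in which changes were planted, and fry called 1 list without changes. Simulated genes were drawn independently, while the estimated correlation in the real lists ran from -0.08 (metallothioneins and zinc) to 0.93 (interferon-stimulated genes). The check therefore cannot show how often the list tests call lists of correlated genes without changes. Trends with GC content, length and expression level were removed with smooth terms in mgcv 1.9.3, and plots were drawn with matplotlib 3.10.9.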

Results

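Gene expression was measured by paired-end RNA sequencing in H929 (NCI-H929), an established line of human multiple myeloma, the cancer of antibody-secreting plasma cells. Cells were kept for 24 h with 1 µM Mi-2, a small-molecule inhibitor of the protease MALT1, or with the solvent DMSO. MALT1 forms a complex with BCL10 and other proteins that passes receptor signals on to the transcription factor NF-κB. The study's title asks about NF-κB signalling downstream of BCMA, a plasma cell surface receptor encoded by TNFRSF17, and about immunogenic cell death, in which dying cells expose or release signals that alert the immune system. There were 3 libraries per treatment, with total estimated counts (to the nearest 100) of 19980700, 22651600 and 21788300 in DMSO libraries 1, 2 and 3 and of 21938900, 23586600 and 23756700 in Mi-2 libraries 1, 2 and 3. No library was a copy of another, since the differences within each group were 16.6 to 23.4 times the chi-square expected from counting alone. Every sample title ends in bio rep 1 and nothing states that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

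After 24 h with Mi-2, H929 cells had lower levels of most measured genes of DNA replication and of some of mitosis, and higher levels of most measured targets of the unfolded protein response. As groups these lists passed camera with a fixed small correlation, but no list passed with an estimated correlation (adjusted p = 0.423, 0.557 and 0.423). Single genes with the largest falls included FCRL2 and FCRL3, neighbouring Fc receptor-like genes of B-lineage cells, and SLC2A5, a fructose transporter. Of 16082 genes tested with edgeR, 808 were higher and 969 lower with Mi-2 at an adjusted p under 0.05, which is 11.05% of those tested. At least 2-fold changes were found for 113 of the higher and 108 of the lower genes, and the median change among called genes was 1.49-fold. In 1776 of the 1777 called genes the CPM ranges of the 2 groups did not overlap. With 3 libraries per group this nearly follows from a call, so it adds no support. The ranges were also separate for 32.3% of all tested genes, where chance gives 10% on average. Genes vary together across the same libraries, so chance can give shares far from that average. Among long non-coding genes (lincRNA or antisense), 53 of 1647 were higher and 10 lower, against 723 higher and 936 lower of 12807 protein-coding genes. Mitochondrially encoded mRNAs took 4.46, 4.23 and 4.66% of the counts in the DMSO libraries and 4.86, 5.05 and 5.00% in the Mi-2 libraries. The counts were smaller without DMSO library 2 (246 higher and 390 lower), DMSO library 3 (275 and 418), Mi-2 library 1 (216 and 302) or Mi-2 library 2 (516 higher). The counts of 2-fold changes were 52 higher without DMSO library 2, 53 higher without DMSO library 3, 38 higher and 49 lower without Mi-2 library 1, and 197 lower without Mi-2 library 3. Limma on the deposited TPM values, with 1 added before the log, called 229 genes higher and 381 lower, and edgeR without a filter on low counts called 1221 higher and 1541 lower.

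**Figure D1:**
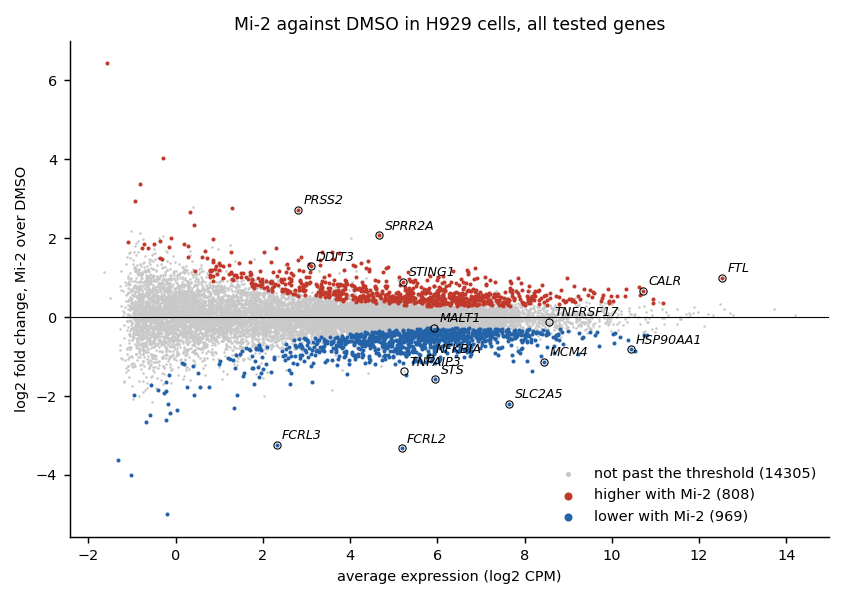
Each point is a tested gene, with its average expression (log2 CPM) on the horizontal axis and its log2 fold change (Mi-2 over DMSO, 3 libraries each) on the vertical axis. The 808 genes past the threshold and higher with Mi-2 are red and the 969 lower are blue, and circles mark labelled genes, among them FCRL2 at -3.33 and FTL at 1.00.

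The largest falls were in FCRL2 (66.1 ± 23.2 CPM with DMSO and 6.58 ± 2.54 CPM with Mi-2, mean ± SD, n = 3) and FCRL3 (8.92 ± 1.04 CPM with DMSO and 0.947 ± 0.241 CPM with Mi-2). Their log2 fold changes were -3.33 ± 0.31 (SE) and -3.23 ± 0.23, or 10.03-fold and 9.40-fold lower, with edgeR adjusted p of 0.00196 and 0.00126. In the GENCODE 29 annotation of GRCh38 the genes lie side by side on the minus strand of chromosome 1, FCRL3 at 157674321 to 157700857 and FCRL2 at 157745733 to 157777132. SLC2A5 (chromosome 1, 9035107 to 9088478, minus strand) was 4.58-fold lower, at 329 ± 75.5 CPM with DMSO and 71.8 ± 14.1 CPM with Mi-2. STS, the steroid sulfatase gene, fell 2.97-fold (-1.57 ± 0.13), NAPSA, which encodes an aspartic protease, 2.79-fold (-1.48 ± 0.17), and PHLDA1 2.72-fold (-1.44 ± 0.17). TERT, the catalytic subunit of telomerase (chromosome 5, 1253147 to 1295069, minus strand), was 2.69-fold lower (-1.43 ± 0.23), and FAM81A (-1.65 ± 0.22), LCAT (-1.39 ± 0.23) and GPR3 (-1.31 ± 0.24) were also among the 12 largest falls. MYB, a transcription factor of blood progenitors, had a larger error (-1.69 ± 0.42, edgeR adjusted p = 0.0327). It was not called without DMSO library 2, DMSO library 3, Mi-2 library 1 or Mi-2 library 2 (highest adjusted p 0.109). GPR3 was not called without DMSO library 2 (adjusted p 0.0513).

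The largest rise was in PRSS2, a trypsinogen gene (1.81 ± 0.725 CPM with DMSO and 11.9 ± 2.17 CPM with Mi-2, log2 fold change 2.72 ± 0.27), followed by SPRR2A, a small proline-rich protein of the epithelial cornified envelope (2.07 ± 0.33). ZNF467 (1.74 ± 0.26), the sulfotransferase genes SULT1A3 (1.65 ± 0.31) and SULT1A4 (1.44 ± 0.17), the heparan sulfatase gene SULF1 (1.63 ± 0.28) and SATB1, a chromatin organiser of lymphoid cells (1.44 ± 0.25), also rose. Among the 12 largest rises were the calcium-binding protein gene S100A6 (1.51 ± 0.30), the RNA genes MIR22HG (1.46 ± 0.32) and SLCO4A1-AS2 (1.65 ± 0.26) and the histone gene H2BC21 (1.41 ± 0.32). Near-identical copies of PRSS2, SPRR2A, SULT1A3, SULT1A4 and H2BC21 exist elsewhere in the genome and could have shared their reads. SLCO4A1-AS2 is an antisense gene, and whether the counting used strand is not given, so its reads cannot be told apart from those of its partner. The calls of H2BC21, MIR22HG and S100A6 were lost without DMSO library 2, DMSO library 3 or Mi-2 library 1 (adjusted p up to 0.0851). H2BC21 was also not called without Mi-2 library 2, nor SULT1A3 without DMSO library 2 (adjusted p 0.0532).

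Genes of DNA replication and the S phase were lower as a group. Of 36 measured members, 34 fell and none rose, and 36 fell when adjusted over the list alone. The median log2 fold change was -0.88 (camera adjusted p = 6.25e-55, and adjusted p = 0.423 with an estimated correlation). MCM10 (-1.17 ± 0.15), GINS1 (-1.16 ± 0.15) and CDC45 (-1.14 ± 0.17), which assemble and activate the replicative helicase, were all over 2-fold lower. MCM4, a subunit of that helicase (chromosome 8, 47960185 to 47978160, plus strand), went from 479 ± 36.4 to 218 ± 42.9 CPM (-1.13 ± 0.14, edgeR adjusted p = 0.00262). Between 29 and 36 members were called lower with any library left out.

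Some genes of the G2 phase and mitosis were lower, with a smaller median fall than the replication genes, a difference that was not tested. Of 30 measured, 13 fell, 21 when adjusted over the list alone. All 30 had negative values, with a median of -0.49 (camera adjusted p = 2.87e-14, and adjusted p = 0.557 with an estimated correlation). Members that fell included the cyclin gene CCNA2 (-0.82 ± 0.13), its kinase partner CDK1 (-0.77 ± 0.13), and AURKB (-0.82 ± 0.17) and BUB1B (-0.78 ± 0.16), whose proteins act in mitosis. The count was 7 without DMSO library 2, 5 without DMSO library 3, 4 without Mi-2 library 1, 6 without Mi-2 library 2 and 22 without Mi-2 library 3. AURKB and BUB1B lost their calls without DMSO library 3, Mi-2 library 1 or Mi-2 library 2 (adjusted p up to 0.0721), and BUB1B also without DMSO library 2, while CCNA2 and CDK1 kept theirs.

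MYC and genes of ribosome biogenesis were also lower. All 30 members measured had negative values, and 16 of them fell, 28 when adjusted over the list alone. Their median was -0.40 (camera adjusted p = 2.87e-14, and adjusted p = 0.557 with an estimated correlation). LYAR (-0.76 ± 0.15), MRTO4 (-0.56 ± 0.10) and NOP56 (-0.58 ± 0.13), which encode nucleolar proteins, and CAD, an enzyme of pyrimidine synthesis (-0.49 ± 0.10), were the members with the largest falls. MYC itself went from 489 ± 24.6 to 356 ± 37.4 CPM (-0.46 ± 0.10, edgeR adjusted p = 0.0196). The count of falls was 1 without DMSO library 2, 5 without DMSO library 3, 2 without Mi-2 library 1 and 8 without Mi-2 library 3. The call of MYC was lost without DMSO library 2, DMSO library 3, Mi-2 library 1 or Mi-2 library 2 (highest adjusted p 0.0809). NOP56 and CAD lost theirs without DMSO library 2 or Mi-2 library 1 (up to 0.0905), NOP56 also without Mi-2 library 3, and LYAR without DMSO library 2 (0.0636). MRTO4 kept its call.

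Targets of the XBP1 and ATF6 arms of the unfolded protein response, which enlarges the folding capacity of the endoplasmic reticulum, were higher. Of 31 measured, 23 rose and none fell, and 27 rose when adjusted over the list alone. The median was 0.54 (camera adjusted p = 3.61e-24, and adjusted p = 0.423 with an estimated correlation). CRELD2 (1.16 ± 0.16), the co-chaperone gene DNAJB9 (1.09 ± 0.17), SEC24D, a component of the COPII transport coat (0.99 ± 0.11), and MANF (0.86 ± 0.11) rose by 1.82-fold to 2.23-fold. CALR, the chaperone calreticulin, is in this list and in that of immunogenic cell death. The count of rises was 12 without DMSO library 2, without DMSO library 3 or without Mi-2 library 1, and the 4 examples kept their calls with any library left out.

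In the integrated stress response, the ATF4-driven programme that other stresses share, 1 of 30 members measured rose and 1 fell, with the same counts when adjusted over the list alone. DDIT3, which encodes the transcription factor CHOP, rose (4.88 ± 0.425 CPM with DMSO and 11.99 ± 4.17 CPM with Mi-2, 1.29 ± 0.24). STC2 fell (-0.44 ± 0.09), and the list had a median of -0.04 (camera adjusted p = 0.825). STC2 was not called without DMSO library 2, DMSO library 3 or Mi-2 library 1 (highest adjusted p 0.0670). Autophagy and lysosome genes were higher, with 12 rises and no fall among 29 measured, and 13 rises when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 1.85e-07, and adjusted p = 0.423 with an estimated correlation). They included GABARAPL1 (0.80 ± 0.14) and MAP1LC3B (0.73 ± 0.13), proteins of the autophagosome membrane, the lysosomal protease gene CTSD (0.79 ± 0.14) and WIPI1 (0.72 ± 0.08). The count of autophagy and lysosome genes was 4 without DMSO library 2 or DMSO library 3 and 5 without Mi-2 library 1. MAP1LC3B lost its call without DMSO library 2 or DMSO library 3 (adjusted p up to 0.0507). CD68, in the list of myeloid markers and itself a lysosomal membrane protein, rose beside them (43.5 ± 5.72 CPM with DMSO and 83.7 ± 13.8 CPM with Mi-2, 0.94 ± 0.14).

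**Figure D2:**
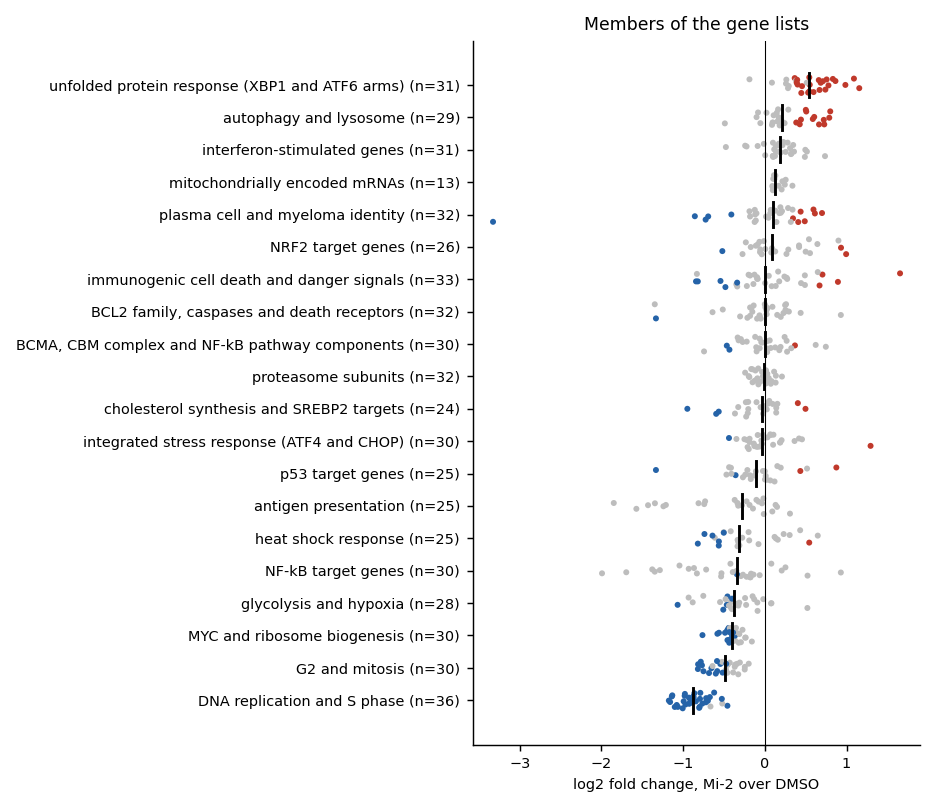
Each point is a measured member of a gene list, placed by its log2 fold change (Mi-2 over DMSO), with red for members past the threshold and higher, blue for lower and grey for the rest. Black bars are list medians, which run from -0.88 for DNA replication to 0.54 for the unfolded protein response. Lists with fewer than 10 measured members are not drawn.

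NF-κB target genes were lower at the median, but their levels varied widely among the DMSO libraries. Only IRF1 passed the threshold among 30 members measured (-0.34 ± 0.08, edgeR adjusted p = 0.0241), and it alone passed when adjusted over the list alone, while without a filter on low counts edgeR called 14 of 40 lower and none higher. Limma on log2(TPM + 1) called none of the targets. In 25 of the 30 the value was negative, with a median of -0.34 (camera adjusted p = 0.0157, and adjusted p = 0.774 with an estimated correlation). TNFAIP3, an inhibitor of NF-κB that NF-κB itself induces, had 14.6, 78.99 and 69.7 CPM in DMSO libraries 1, 2 and 3 and 8.94, 24.1 and 29.8 CPM in Mi-2 libraries 1, 2 and 3. NFKBIA, which encodes IκBα, had 25.3, 128 and 77.6 CPM in DMSO libraries 1, 2 and 3 and 22.9, 47.99 and 41.1 CPM in Mi-2 libraries 1, 2 and 3. Their log2 fold changes, -1.38 ± 0.55 and -1.04 ± 0.47, did not pass (edgeR adjusted p = 0.142 and 0.185). The mean log2 CPM of the list differed by -0.41 between the groups (exact permutation p = 0.3, two-sided, where 0.1 is the smallest that 3 against 3 allows). The permutation took no account of the library numbers. Between libraries of the same number, Mi-2 minus DMSO ran from -0.68 to -0.03, negative for each number. With the number as a block more members were called, as given below, though the labels name no pairs. Without DMSO library 2 the list median was -0.16 and the list did not pass (camera adjusted p = 0.261). Without DMSO library 1, which had the lowest TNFAIP3 and NFKBIA of the 3 DMSO libraries, the median was -0.56 and 11 members were called lower, TNFAIP3 and NFKBIA among them (adjusted p = 0.0173 and 0.0166). IRF1 was called only in the fit without Mi-2 library 3 among the 6 fits that left a library out (highest adjusted p 0.0886).

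Few genes of the pathway itself passed the threshold. TNFRSF17, which encodes BCMA, stood at 395 ± 60.01 CPM with DMSO and 364 ± 45.00 CPM with Mi-2 (log2 fold change -0.12 ± 0.13, edgeR adjusted p = 0.611). MALT1, the target of the compound, had 66.1 ± 2.94 CPM with DMSO and 54.8 ± 4.46 CPM with Mi-2 (-0.27 ± 0.09, edgeR adjusted p = 0.0793) and did not pass the threshold. BCL10 had a value close to 0 with an error larger than the value (0.03 ± 0.15). Of 30 components measured, TAB2 rose (0.37 ± 0.09). TRAF3 (-0.47 ± 0.10) and TRAF2 (-0.43 ± 0.12), adaptors that hold back the non-canonical NF-κB kinase, fell. The list had a median of -0.00210 (camera adjusted p = 0.973). Adjusted over the list alone, 1 rose and 1 fell. With a library left out, TRAF2 was called only without Mi-2 library 2 and TAB2 only without Mi-2 library 3 (adjusted p otherwise up to 0.160). TRAF3 lost its call without DMSO library 2, DMSO library 3 or Mi-2 library 1 (up to 0.0918). None of the 3 was called by limma on log2(TPM + 1).

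**Figure D3:**
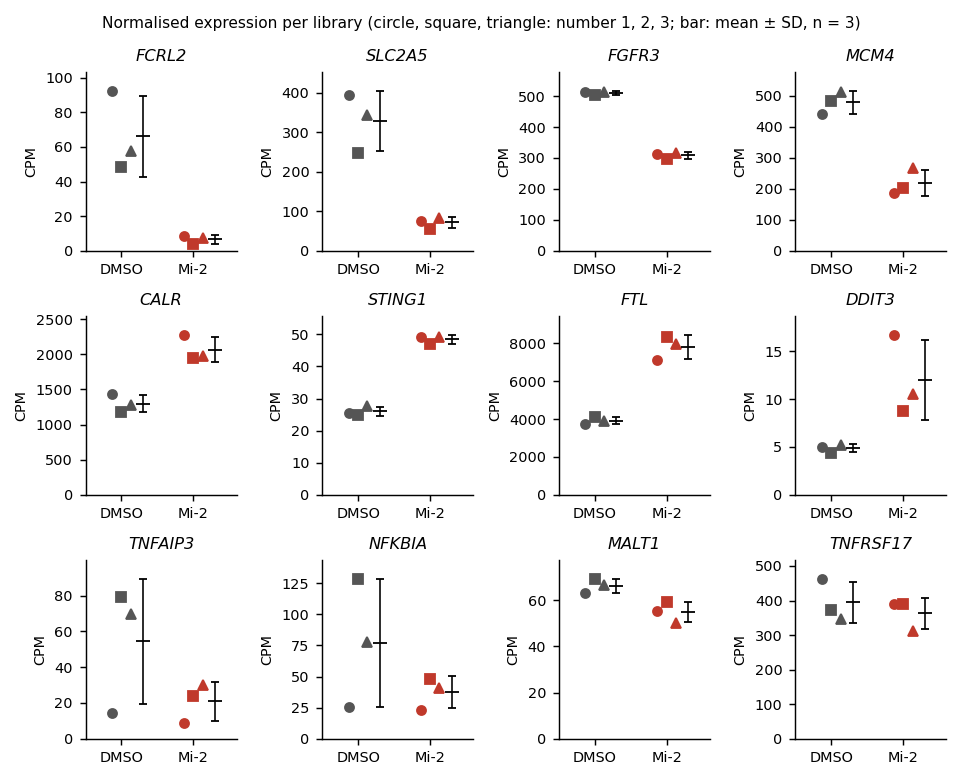
Normalised expression (CPM, linear axis from 0) of 12 genes in each library, with circles, squares and triangles for libraries 1, 2 and 3 of each treatment and a bar for the mean ± SD (n = 3). FGFR3, MCM4, SLC2A5 and FCRL2 lie lower and CALR, STING1, FTL and DDIT3 higher in every Mi-2 library than in every DMSO library, whereas TNFAIP3, NFKBIA and TNFRSF17 overlap.

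Genes linked to immunogenic cell death and danger signals moved both ways. Of 33 measured, 4 rose and 5 fell, or 6 and 7 when adjusted over the list alone. The list did not pass as a whole (median 0.00, camera adjusted p = 0.582). CALR, which serves as an uptake signal when exposed on dying cells (chromosome 19, 12938578 to 12944489, plus strand), rose from 1298 ± 125 to 2065 ± 181 CPM (0.67 ± 0.11, edgeR adjusted p = 0.00697). Its partner PDIA3 (0.71 ± 0.11), the DNA-sensing adaptor STING1 (26.1 ± 1.41 CPM with DMSO and 48.5 ± 1.34 CPM with Mi-2, 0.90 ± 0.09) and ANXA1 (1.66 ± 0.19) rose too. HMGB1, a nuclear protein that acts as a danger signal outside the cell, fell (262 ± 20.03 CPM with DMSO and 188 ± 15.9 CPM with Mi-2, -0.48 ± 0.10), as did the DNA sensor gene CGAS (-0.54 ± 0.12), HSP90AA1 (-0.82 ± 0.13) and ENTPD1, an enzyme that degrades extracellular ATP (-0.84 ± 0.18). The remaining fall was in CD47, a signal against uptake, named after its values were seen (-0.34 ± 0.09). The calls of CALR, PDIA3, STING1, ANXA1 and HSP90AA1 held with any library left out. The call of HMGB1 was lost without DMSO library 3 or Mi-2 library 1 (adjusted p up to 0.0663). CGAS was not called without DMSO library 2, Mi-2 library 1 or Mi-2 library 3 (up to 0.0892), nor ENTPD1 without DMSO library 2, DMSO library 3 or Mi-2 library 1 (up to 0.0726). The count of falls was 2 without DMSO library 2, 3 without DMSO library 3 and 1 without Mi-2 library 1. These are mRNA levels, and exposure or release of the proteins was not measured.

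Genes of plasma cell and myeloma identity also moved in both directions, with 7 rises and 5 falls among 32 measured, and the same counts when adjusted over the list alone. The median and mean differed in sign (median 0.10, mean -0.04, camera adjusted p = 0.533). Beside FCRL2, FGFR3, a receptor tyrosine kinase gene (chromosome 4, 1793293 to 1808872, plus strand), fell from 509.7 ± 6.48 to 308 ± 10.7 CPM (-0.72 ± 0.08, edgeR adjusted p = 0.00209). The plasma cell surface genes CD38 (-0.86 ± 0.21) and SDC1, which encodes CD138 (-0.69 ± 0.15), fell. MZB1 (0.70 ± 0.11), DERL3 (0.61 ± 0.16) and FKBP11 (0.60 ± 0.08), which act in the endoplasmic reticulum of secretory cells, rose, as did the surface receptor gene GPRC5D (0.49 ± 0.12). IRF4, the transcription factor on which myeloma cells depend, went from 1726 ± 140.4 to 2192 ± 26.6 CPM (0.35 ± 0.09, edgeR adjusted p = 0.0441). The calls of FGFR3, MZB1 and FKBP11 held with any library left out. CD38 lost its call without DMSO library 2, Mi-2 library 1 or Mi-2 library 3 (adjusted p up to 0.105), and SDC1 without DMSO library 2 or Mi-2 library 2 (up to 0.0692). With a library left out, IRF4 and DERL3 were called only without DMSO library 1 and GPRC5D only without Mi-2 library 3 (adjusted p otherwise up to 0.165). The count of rises was 2 without DMSO library 2, 3 without DMSO library 3, 3 without Mi-2 library 1 and 4 without Mi-2 library 2. The count of falls was 2 without DMSO library 2 and 3 without each of the Mi-2 libraries in turn.

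Heat shock genes were lower at the median, with 6 falls and 1 rise among 25 measured, and 10 falls and 1 rise when adjusted over the list alone. Their median was -0.31 (camera adjusted p = 0.00460, and adjusted p = 0.658 with an estimated correlation). The cytosolic and mitochondrial chaperone genes HSP90AA1 (1757 ± 124 CPM with DMSO and 995 ± 178 CPM with Mi-2), HSPD1 (-0.74 ± 0.14), FKBP4 (-0.64 ± 0.11) and HSPH1 (-0.56 ± 0.15) fell, and SERPINH1, a chaperone of the endoplasmic reticulum, rose (0.54 ± 0.14). Without DMSO library 2 there were 3 falls and the list did not pass (camera adjusted p = 0.0658). HSPD1 lost its call without DMSO library 2 (adjusted p 0.0616), and with a library left out HSPH1 was called only without Mi-2 library 2 and SERPINH1 only without Mi-2 library 1 (adjusted p otherwise up to 0.140). Genes of glycolysis and hypoxia had 5 falls among 28 measured, 7 when adjusted over the list alone, and a median of -0.38 (camera adjusted p = 2.09e-04, and adjusted p = 0.658 with an estimated correlation). The glycolytic enzyme genes ENO2 (-1.07 ± 0.26), PFKP (-0.47 ± 0.12) and ENO1 (-0.46 ± 0.11) and the regulator PFKFB3 (-0.51 ± 0.12) were among them. No glycolysis gene was called without DMSO library 2, DMSO library 3 or Mi-2 library 1, and 3 were without Mi-2 library 2 or Mi-2 library 3.

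Of 26 targets measured of NRF2, the transcription factor of the oxidative stress response, 2 rose and 1 fell, or 4 and 1 when adjusted over the list alone. Their median was 0.08 (camera adjusted p = 0.0486, and adjusted p = 0.658 with an estimated correlation). FTL, the light chain of the iron store ferritin, rose from 3922 ± 184 to 7819.6 ± 626 CPM (1.99-fold, 1.00 ± 0.10, edgeR adjusted p = 0.00201). BLVRB, a biliverdin reductase, rose 1.91-fold (0.93 ± 0.11), while PGD of the pentose phosphate pathway fell (-0.52 ± 0.13). The NRF2 list did not pass without DMSO library 1, DMSO library 2, Mi-2 library 2 or Mi-2 library 3 (camera adjusted p up to 0.268), nor without abundant genes (0.216) or without a filter on low counts (0.0694), where 7 members rose. FTL was itself among the abundant genes left out, so that fit tested the list without it. DESeq2 called 4 higher. In single members, 4 rose without DMSO library 1, and PGD was not called without DMSO library 2, DMSO library 3 or Mi-2 library 1 (adjusted p up to 0.115). FTL, HMGB1, HSPD1 and HSP90AA1 have processed pseudogenes that could share their reads. Of 24 cholesterol synthesis genes measured, 3 fell, DHCR7 (-0.60 ± 0.12) and ACAT2 (-0.56 ± 0.15) among them, and HSD17B7 (0.50 ± 0.11) and HMGCS1 (0.40 ± 0.11) rose. Adjusted over the list alone there were 4 falls and 2 rises (list median -0.04, camera adjusted p = 0.287). None of these 4 named genes was called without DMSO library 2 or DMSO library 3 (adjusted p up to 0.157 for HMGCS1 and 0.144 for ACAT2 over the 6 fits). None of the 4 was called without Mi-2 library 1 and only DHCR7 without Mi-2 library 2, and HSD17B7 was not called without DMSO library 1.

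Among 25 p53 targets, PMAIP1, which encodes the pro-apoptotic protein NOXA (8.55 ± 1.77 CPM with DMSO and 3.40 ± 0.813 CPM with Mi-2, -1.33 ± 0.23), and AEN (-0.36 ± 0.08) fell and TP53INP1 (0.88 ± 0.14) and BTG2 (0.43 ± 0.09) rose. Adjusted over the list alone there were 4 falls and 2 rises (median -0.11, camera adjusted p = 0.489). AEN and BTG2 were not called without DMSO library 2, DMSO library 3 or Mi-2 library 1, nor AEN without DMSO library 1 (adjusted p up to 0.104), and 4 members fell without Mi-2 library 2. PMAIP1 was also the only member past the threshold among 32 genes of the BCL2 family, caspases and death receptors, and again when adjusted over the list alone (median 0.00366, camera adjusted p = 0.844). A further member of that list was called without DMSO library 1, and 2 without Mi-2 library 3, and edgeR without a filter on low counts called 1 higher and 3 lower. None of 31 interferon-stimulated genes (median 0.18, camera adjusted p = 0.122), 25 antigen presentation genes (median -0.28, 0.122), 32 proteasome subunits (median -0.00459, 0.653) and 6 metallothionein and zinc genes (median -0.08, 0.653) passed, over all genes or adjusted over the list alone. A zinc response gene was called without Mi-2 library 2, and an antigen presentation gene without Mi-2 library 2 or Mi-2 library 3. The interferon list passed without DMSO library 1 (camera adjusted p = 0.0383), DMSO library 2 (3.04e-04) or Mi-2 library 3 (5.76e-05), and the antigen presentation list without DMSO library 1 (2.07e-04), where 3 of its members were called lower. Without a filter on low counts both passed (0.0428 and 0.0144), with 8 interferon genes higher and 1 lower and 12 antigen presentation genes lower and 1 higher. Both also passed with the library number as a block (camera adjusted p = 5.08e-04 and 3.42e-04), where members of each were called, as given below.

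All 13 mitochondrially encoded mRNAs had positive values, none past the threshold over all genes or adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0359, and adjusted p = 0.658 with an estimated correlation). The list did not pass without DMSO library 1, DMSO library 2, Mi-2 library 2 or Mi-2 library 3 (camera adjusted p up to 0.236), nor with abundant genes left out (0.148), and 1 member was called without DMSO library 3. Leaving out abundant genes removes any list members among them, so that fit may have tested a smaller list. Of the markers of other cell types, CD68 was the only one of 13 myeloid genes measured and rose (camera adjusted p = 0.00474, and adjusted p = 0.423 with an estimated correlation, for a list of 1 gene), a list that did not pass without a filter on low counts (0.111). Of 5 fibroblast, endothelial and epithelial markers measured, KRT18 (7.30 ± 1.51 CPM with DMSO and 15.3 ± 2.14 CPM with Mi-2, 1.07 ± 0.18) and PECAM1 (0.35 ± 0.10) rose, while FN1 had 0.18 ± 0.21 and did not pass. For the list as a whole the tests gave camera adjusted p = 0.0130, and adjusted p = 0.557 with an estimated correlation. That list did not pass without DMSO library 1 or any of the Mi-2 libraries, and PECAM1 was called in none of the 6 fits that left a library out. Of 2 T and NK cell markers measured, CD3E rose (29.5 ± 3.15 CPM with DMSO and 41.7 ± 2.94 CPM with Mi-2, 0.50 ± 0.11), except without DMSO library 2 (adjusted p 0.0783), and the list did not pass (camera adjusted p = 0.122). Of 3 erythroid and platelet markers measured, none passed (camera adjusted p = 0.653). The T and NK and the erythroid lists passed without DMSO library 3 (0.0310 and 0.0464). These calls were the same when adjusted over each list alone.

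Of the 25 lists, 6 were lower and 6 higher by camera, which assumes a small fixed correlation between genes. With the correlation estimated from these libraries none of the 25 passed, and with fry, which asks whether the genes of a list move on balance in a single direction, only DNA replication did (adjusted p = 0.0455). Other splits of the 6 libraries gave 5 to 14 lists past the camera threshold, but these mix the treatments unevenly and so keep part of any Mi-2 difference. Of the 96 named genes 89 passed the threshold, and 46 of these kept their call with any library left out.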

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

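The alternatives were chosen before the data were examined, except those for the clustered histone genes. No call among the 1777 genes turned to a call in the opposite direction in any alternative. With RLE or upper-quartile scaling, DESeq2, limma-voom, a filter of 1 CPM, or immunoglobulin and abundant genes left out, the count of higher genes was 795 to 992 (main value 808) and of lower genes 849 to 1260 (969). Without a filter on low counts edgeR called 1221 higher and 1541 lower, 210 and 206 of them at least 2-fold, and the cause was not tested. Limma on log2(TPM + 1) called 229 and 381 (31 and 47 at least 2-fold) and on log2(TPM + 0.1) 249 and 398 (53 at least 2-fold higher), and the cause was not tested. Limma on log2(TPM + 1) with no TPM filter called 0 higher and 0 lower, also 0 of at least 2-fold, of 31463 genes, with 3808 at an unadjusted p under 0.05, against 808 and 969 by edgeR. Leaving out a library, which lowers the number of samples, gave 216 to 715 higher and 302 to 866 lower, 38 to 140 at least 2-fold higher and 49 to 197 at least 2-fold lower, lowest without Mi-2 library 1. Of the 96 named genes, 41 lost their call without DMSO library 2, 34 without Mi-2 library 1, 33 without DMSO library 3, 18 without Mi-2 library 2, 10 without Mi-2 library 3 and 9 without DMSO library 1, and none reversed.

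Of the 25 lists 12 passed with camera, 9 to 14 with a library left out, 0 with an estimated correlation and 1 with fry. For the NF-κB target list the adjusted p was 0.774 with an estimated correlation and 0.413 with fry, against 0.0157, and the cause was not tested. With a library left out it ran from 7.39e-09 (without DMSO library 1) to 0.261 (without DMSO library 2), and it was 0.0156 with RLE scaling, 1.40e-04 without a filter and 0.0158 with abundant genes left out. Apart from the library number as a block, given below, the list test was not run with the other alternatives. Counts of called members also moved. Without a filter, 14 NF-κB targets, 25 G2 and mitosis, 25 MYC, 15 glycolysis, 12 heat shock, 12 antigen presentation, 6 p53 and 3 BCL2 family genes were lower (1, 13, 16, 5, 6, 0, 2 and 1 with it), and 8 interferon genes and 7 NRF2 targets higher (0 and 2). DESeq2 called 10 heat shock, 8 glycolysis and 4 p53 genes lower and 4 NRF2 targets higher. Limma on log2(TPM + 1) called 11 unfolded protein response and 4 autophagy genes higher (23 and 12 by edgeR), and 7 G2 and mitosis, 8 MYC, 2 heat shock, 2 danger signal and 1 glycolysis genes lower (13, 16, 6, 5 and 5). It also called 3 higher and 3 lower of plasma cell identity (7 and 5), 1 and 1 of cholesterol synthesis (2 and 3), 1 p53 target lower (2), 1 fibroblast, endothelial or epithelial marker higher (2), no heat shock gene higher (1), no NRF2 target lower (1), and none of the NF-κB targets (1 lower) or pathway components (1 higher and 2 lower). For the clustered histone genes, 9 of 30 were higher in the fit used throughout and with either other scaling, and 1 to 10 with a library left out. Few counts limit these data for genes near the filter, and 3 libraries per group limit small changes. In the simulation 36% of 1.5-fold changes were found. Far fewer genes were changed there (200) than were called here (1777), so that share cannot be carried over to the real data.

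The library numbers were checked for pairing. Across genes, the deviations from the group mean of same-numbered DMSO and Mi-2 libraries correlated by 0.41, 0.06 and 0.26 for numbers 1, 2 and 3. These correlations alone neither show nor exclude pairs, and the labels name none, so the fit without a block, fixed in advance, stayed the main one. In 5 of the 6 libraries the highest correlation was with the same number, the exception being Mi-2 library 2 (0.08 with DMSO library 3), which is a hint from the data and not the design. The haemoglobin genes HBA1 and HBG1, given at the end, also followed the number in both treatments. So did PC2, a principal component (an axis that summarises the expression of all genes) with 23.1% of the variance. It was 39.2, 3.98 and -14.7 in DMSO libraries 1, 2 and 3 and 13.5, -17.1 and -24.9 in the Mi-2 libraries. On PC1 and PC3 the order of the numbers was also alike in both treatments, and on PC4 it was not. If the numbers do mark pairs, the main fit calls too few genes. With the number as a replicate block edgeR called 1791 higher and 2035 lower, 164 and 167 of them at least 2-fold. All 808 and 969 genes called without the block were among them, and the NF-κB list had an adjusted p of 7.13e-04, with 11 members lower and 2 higher. The interferon and antigen presentation lists passed (5.08e-04 and 3.42e-04, with 10 higher and 2 lower, and 1 higher and 13 lower), and no other list call changed. Of NRF2 targets 10 were higher and 3 lower, and of BCL2 family and death receptor genes 5 and 4. Among the 30 clustered histone genes 14 were higher and none lower.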

Other observations

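The 9 added lists, clustered histones among them, and the tests of explanations in this part were chosen or written down only after the results were seen, namely those on the replication genes, the histones, the NF-κB list, markers of other cell types and the divisions of the libraries. Camera adjusted p-values of the 9 added lists are over 34 lists, these 9 and the earlier 25, and all others are over the 25. Genes of homologous recombination and the Fanconi pathway, which repair broken and crosslinked DNA, were lower beside the replication genes. Of 30 measured, 24 fell and none rose, with a median of -0.76 (camera adjusted p = 2.33e-26, and adjusted p = 0.317 with an estimated correlation). The exonuclease gene EXO1 (-1.17 ± 0.17, SE), XRCC2 (-1.10 ± 0.17) and BRCA1 (-0.84 ± 0.09) were among them. Of 18 purine and pyrimidine synthesis genes 10 fell, such as the CTP synthase gene CTPS1 (-0.72 ± 0.12) and DTYMK (-0.77 ± 0.11), with a median of -0.38 (camera adjusted p = 5.11e-10, and adjusted p = 0.325 with an estimated correlation). None of 79 cytosolic ribosomal protein genes (median 0.01) and none of 20 tRNA synthetase genes (median -0.12) passed with edgeR. FCRL3 was the only called gene among 5 members of the FCRL family other than FCRL2.

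Some genes of protein transport, glycosylation and lysosomes were higher, fewer than 50% of each list. Of 37 genes of transport between the endoplasmic reticulum and Golgi, all 37 had positive values and 17 rose, with a median of 0.37 (camera adjusted p = 1.68e-16, and adjusted p = 0.325 with an estimated correlation). They included the cargo receptor gene TMED9 (0.69 ± 0.10), KDELR2, which returns escaped proteins (0.65 ± 0.09), and the COPI coat gene COPG1 (0.53 ± 0.09). Of 25 genes of protein glycosylation and translocation at the endoplasmic reticulum 11 rose, such as DDOST (0.56 ± 0.12) and SSR2 (0.54 ± 0.10), with a median of 0.34 (camera adjusted p = 1.97e-09, and adjusted p = 0.394 with an estimated correlation). Of 29 lysosomal enzyme and membrane protein genes 10 rose, such as SMPD1 (0.61 ± 0.11) and NEU1 (0.59 ± 0.11), with a median of 0.15 (camera adjusted p = 3.79e-04, and adjusted p = 0.325 with an estimated correlation).

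Replication genes fell, but of 30 clustered histone genes, whose mRNAs normally rise with DNA replication and mostly lack a poly(A) tail, 9 rose and none fell, with a median of 0.91, among them H2BC4 (1.32 ± 0.36) and H1-2 (0.89 ± 0.15) (camera adjusted p = 3.46e-07, and adjusted p = 0.381 with an estimated correlation). Only 1 rose without DMSO library 3 or Mi-2 library 1, 4 without DMSO library 2 and 5 without Mi-2 library 2. The median log2 fold change in these fits was, in the same order, 0.84, 0.68, 0.83 and 0.91. Once trends with GC content, length and expression level were removed, the medians were -0.86 (95% interval -0.91 to -0.76) for the replication genes and 0.78 (0.58 to 1.02) for the histones, which argues against such a trend as the cause. The intervals in this paragraph come from resampling the genes of a list in the same libraries, so they do not measure spread between libraries. Reads moved between near-identical histone copies would leave their sum alike, but the summed histone CPM was 1.61-fold higher, at 693, 527 and 476 in the Mi-2 libraries against 383, 369 and 300 in the DMSO libraries. More carry-over of RNA without a tail into the Mi-2 libraries cannot be told apart from a response to Mi-2, since only 5 small RNAs without a tail were measured (median 0.22, 95% interval -0.46 to 0.30). Histone mRNAs with a tail in cells that divide less would be such a response, a hypothesis that was not tested.

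The fall of the NF-κB target list came with a wide spread between libraries. The mean log2 CPM of its members was 3.57, 4.58 and 4.32 in DMSO libraries 1, 2 and 3 and 3.54, 3.90 and 3.81 in Mi-2 libraries 1, 2 and 3. DMSO libraries 2 and 3 were both above DMSO library 1, so the list result depends on which is left out. Without DMSO library 2 the median was -0.16 and the list did not pass (camera adjusted p = 0.261), and without DMSO library 1 the median was -0.56 and the list passed (7.39e-09). DMSO library 2 was not alone, since DMSO library 3 (4.32) also lay above every Mi-2 library, while DMSO library 1 (3.57) lay above Mi-2 library 1 only. Between libraries of the same number, Mi-2 minus DMSO ran from -0.68 to -0.03, negative for each number, though the labels do not pair them. How much of the fall comes from high NF-κB targets in DMSO library 2 remains open.

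Of 11 tested markers of other cell types CD68, CD3E, KRT18 and PECAM1 rose with Mi-2. For CD68 and CD3E the values of the other markers argue against other cells in the cultures, and for KRT18 they do not decide. PECAM1 rose by 17.5 CPM, with VWF highest of the other 2 endothelial markers at 0.0281 CPM. The rise of CD68 was 39.9 CPM, while the other 12 myeloid markers rose by 0.279 CPM in sum and the highest of them, LYZ, stood at 0.371 CPM. The rise of CD3E was 12.1 CPM, and the other 14 T and NK markers rose by 0.785 CPM in sum, with CD247 highest at 2.55 CPM. The rise of KRT18 was 7.93 CPM, and KRT8, KRT19, EPCAM and CDH1 rose by 1.32 CPM in sum, with KRT8 highest at 2.75 CPM. These markers were so low that a rise in proportion to KRT18 would also have been small in CPM. KRT8 went from 2.04 to 2.75 CPM and CDH1 from 0.930 to 1.58 CPM. KRT19 went from 0.134 to 0.140 CPM and EPCAM from 0.168 to 0.126 CPM. Expression of CD68, CD3E and KRT18 by the myeloma cells themselves, changed by Mi-2, may account for this, as a hypothesis that staining of single cells for these proteins and a plasma cell marker would decide.

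The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 808 higher and 969 lower, 113 and 108 of them at least 2-fold, and the highest count in any other division was 0 for each, so 1 of 10 divisions, the real one, reached each count. At an unadjusted edgeR p under 0.05 there were 4347 genes in the real division and at most 1368 in another. For the lists, the real division gave 12 past the camera threshold and the highest other 14, and 3 of the 10 divisions gave as many as the real one. DMSO library 1, Mi-2 library 1 and Mi-2 library 2 against the rest gave those 14, with medians (rest minus that side) of 0.44 for replication and -0.36 for the unfolded protein response. Each division other than the real one mixes the treatments unevenly. It therefore keeps part of any Mi-2 difference and does not show what chance alone gives. The median of the replication list was 0.88 in size in the real division against at most 0.47 in others, that of the unfolded protein response 0.54 against 0.36, and that of the NF-κB targets 0.34 against 0.56.

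The haemoglobin genes HBA1 and HBG1 had 0 CPM each in DMSO library 1, 2.47 and 2.25 in DMSO library 2, 3.12 and 3.30 in DMSO library 3, 0.0912 and 0 in Mi-2 library 1, 1.82 and 2.37 in Mi-2 library 2, and 3.66 and 3.58 in Mi-2 library 3. In both treatments they rose from library 1 to library 3, a likeness by library number, though at few CPM. HBB, also tested, did not rise at each step with Mi-2 (0.593, 0.551 and 1.14 CPM in libraries 1, 2 and 3).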
